A study of Mus musculus with 6 samples.

How the data were processed

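Small RNA was profiled in 6 mouse cell populations that had been sorted by flow cytometry after injection of a lentiviral vector that carries green fluorescent protein. Per the labels, cells were sorted for the fluorescent protein and for surface markers: B cells as CD45 and CD19 positive, cDC1 (type 1 conventional dendritic cells) as CD45, CD11c and CD8a positive, and cDC2 (type 2) as CD45, CD11c and CD11b positive. Red pulp macrophages (RPM) and Kupffer cells, the resident macrophages of spleen and liver, shared the gate CD45 and F4/80 positive. Liver sinusoidal endothelial cells (LSEC) were CD45 negative and CD31 positive. Each population was 1 pool of 3 animals with 500000 to 3000000 cells. Organs were digested with collagenase, dispase and DNase before sorting, per the labels' protocols. RNA was extracted with a miRNeasy kit, and libraries were made with the QIAseq miRNA kit, which attaches a unique molecular identifier (UMI) to each molecule before amplification.

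The deposited tables give UMI counts and read counts per miRNA, piRNA, transfer RNA and other RNA, and a count of reads per class, per the file headers. The aligner, the genome build and the miRNA reference are not given in the sources used here. The tables hold 1901 miRNA rows, 470 piRNA rows, 429 transfer RNA rows and 5761 rows of other RNA. No value from 1 to 9 occurs in any of them, so a count under 10 is listed as 0. The read classes sum to the total reads in all 6 libraries. 12 miRNA rows combine mature miRNAs that the authors counted jointly, as with miR-199a-3p and miR-199b-3p, and they are used as such.

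UMI counts were divided by the sum of all miRNA UMIs of the library and multiplied by 1000000 (CPM). This unit is a share: where a few miRNAs take a large part of a library, all others read lower. UMIs remove amplification copies but not differences in ligation efficiency between sequences, so levels of different miRNAs within a library are less comparable than levels of 1 miRNA between libraries. The libraries held 2800611 (B cells) to 24720360 (LSEC) miRNA UMIs, so that 10 UMIs correspond to 3.57 CPM in B cells and to 0.405 in LSEC.

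There was 1 library per population. No test across replicates can be made, no p-value is given, and no spread between animals is known. Folds carry an exact 95% Clopper-Pearson interval of the UMI counts, single levels an exact Poisson interval, and shares a Wilson interval. All of these cover counting error only and compare libraries, not populations in general. For a fold against a library listed at 0, that library was set to 10 UMIs. The floor planned before the data were examined was 3, which these tables cannot support.

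Rules of size, fixed before the data were examined, replaced tests. A miRNA marked a population when it was at least 4-fold above the highest of the 5 other libraries. In the 3 pairwise comparisons (Kupffer cells against RPM, Kupffer cells against LSEC, cDC1 against cDC2) the fold was also 4. For a pair of populations, the lower of the 2 libraries had to be at least 2-fold above the highest of the 4 others. Every rule required 100 CPM in the higher library, or for a pair in the lower of both. Ranks of the pairwise comparisons and list medians used log2(CPM + 10), which understates the change of low miRNAs. Ranks per population and per shared set used the plain fold, without an added value. The text names miRNAs from among the list members, the 5 most abundant miRNAs of each library, the 6 with the largest fold per population and per shared set, and the 10 with the largest change in each direction of a pairwise comparison.

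A total of 17 miRNA lists, with 96 entries that were all found in the tables, had been fixed beforehand from general knowledge. They were B cell and lymphocyte, macrophage and myeloid, endothelial, pan-haematopoietic, inflammation-responsive, miR-342 locus, hepatocyte, erythroid, stellate and mesenchymal, epithelial miR-200, miR-17-92 cluster, miR-23-27-24 clusters, let-7 family, miR-29 family, miR-30 family, Dlk1-Dio3 imprinted cluster and proliferation-linked miR-15/16. Some share members, as miR-150-5p is in the B cell and pan-haematopoietic lists. Each list's median log2 difference was placed among the medians of 10000 random lists of the same size, matched by decile of mean expression, drawn from 306 miRNAs. This percentile describes these libraries and is not a p-value. Spearman correlations were taken across the 295 miRNAs at 100 CPM or more in any library; miRNAs are not independent replicates.

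Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 for scaling factors only. The fold rule was tested on simulated counts of 1901 miRNAs, some of them changed by a known fold. Counts were drawn with Poisson error only, from the profile of the second library and with the totals held fixed. Changed miRNAs differed 2-fold or 8-fold, so with a limit of 4 the calls were largely fixed beforehand. Spread between animals, shifts of composition and a raised background were not simulated. For Kupffer cells against RPM it called 98 of 98 miRNAs changed 8-fold, 0 of 75 changed 2-fold and 0 of 63 unchanged. The 95% intervals held the true fold for 95.9% of the 8-fold, 93.3% of the 2-fold and 93.7% of the unchanged miRNAs of that comparison. Coverage was lower for the 8-fold miRNAs of Kupffer cells against LSEC (90.8%) and for the 2-fold (90.7%) and unchanged miRNAs (91.1%) of cDC1 against cDC2.

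Alternatives were read counts in place of UMIs, edgeR TMM factors, DESeq2 size factors, all UMIs of any RNA class as the total, and a total without the 3 most abundant miRNAs of any library. The last 4 were rescaled so that the mean log total stayed the same. Others were minimums of 10 or 1000 CPM, the lower interval end in place of the fold, folds of 2 (or 4 for pairs), the median of the other libraries, pseudocounts of 1 or 50, and lists without their most abundant member. Subtraction of each library's median miRNA row from all its rows, and omission of the Kupffer cell library, were added after the data had been seen. The 6 miRNAs named for shared repeats, the non-coding transcripts and the transfer RNA isotypes were chosen after the values had been seen. Locations of miRNA genes are from GENCODE M21 on GRCm38, matched by gene name; they were not used for counting. Of the 5761 other RNA rows, 5606 matched a transcript of that annotation by identifier. Protein-coding transcripts are given only as a class total, so marker genes of other cell types could not be followed in them.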

Results

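Small RNA libraries of 6 sorted mouse populations were compared to find which miRNAs differ among the cells that a systemically injected lentiviral vector reaches. B cells, cDC1, cDC2 and red pulp macrophages (RPM) came from spleen, and Kupffer cells and liver sinusoidal endothelial cells (LSEC) from liver. The series' title places the work in a study of miR-342 in macrophages around liver metastases. Each population was 1 pooled library, so there was no replicate spread to set a difference against, and intervals cover counting error only. Levels are UMIs (unique molecular identifiers, 1 per counted molecule) per 1000000 miRNA UMIs, written CPM.

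Total reads ranged from 19628834 (B cells) to 45656264 (LSEC). miRNA UMIs numbered 2800611 in B cells, 10759946 in cDC1, 10607276 in cDC2, 5663664 in RPM, 3702295 in Kupffer cells and 24720360 in LSEC. The RNA classes differed widely. miRNA made up 77.2% of LSEC reads, 53.5% of cDC2 reads and 44.1% of cDC1 reads, against 24.5% in RPM, 17.2% in B cells and 11.2% in Kupffer cells. In RPM, 33.3% of reads were transfer RNA, the class that took 1.82% to 6.05% elsewhere. Kupffer cells had 32.7% of reads in other RNA, 14.5% mappable but uncharacterised and 4.87% in messenger RNA, and 51.2% of B cell reads lacked the adapter. The Kupffer cell library also differed at the low end: its median miRNA row stood at 37.0 CPM, against 1.66 (LSEC) to 7.59 (RPM) in the others.

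**Figure D1:**
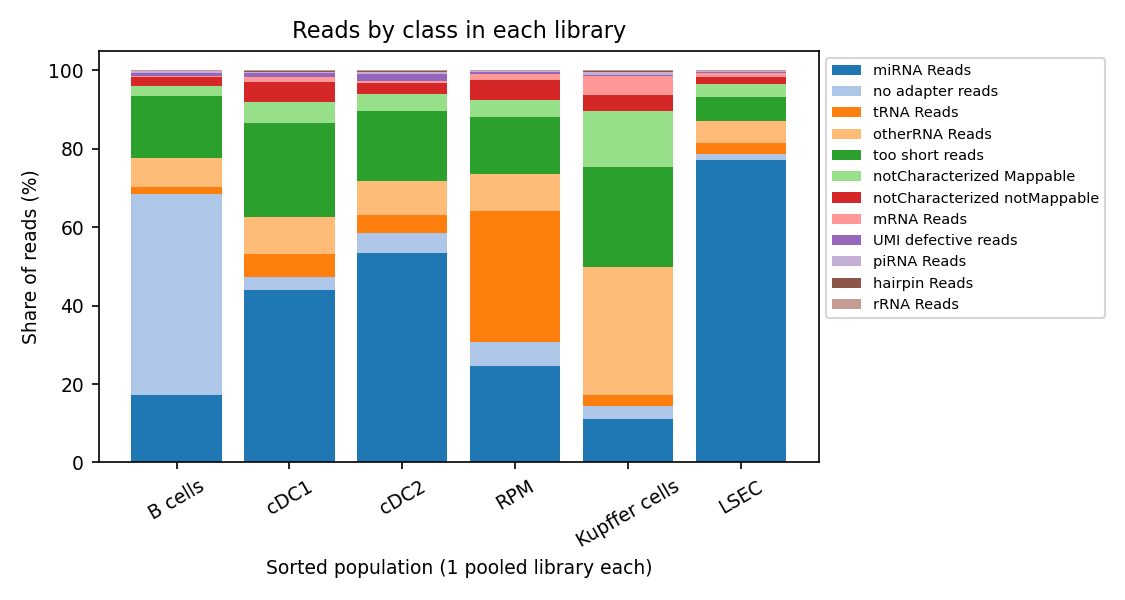
Share of reads (%) in each class, stacked, for the 6 libraries (1 pooled library per population). miRNA reads range from 11.2% in Kupffer cells to 77.2% in LSEC, transfer RNA takes 33.3% in RPM, and 51.2% of B cell reads have no adapter.

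miR-142a-3p, a miRNA of blood cells, stood at 123489 CPM in B cells, 135381 in cDC1 and 152513 in cDC2. It was lower in RPM (22283) and Kupffer cells (23442) and far lower in LSEC (205). miR-126a-3p, the classical endothelial miRNA, reached 254039 in LSEC, where its partner miR-126a-5p stood at 109674 and miR-26a-5p at 47308. miR-16-5p lay between 63727 (LSEC) and 148496 (cDC2), and let-7a-5p and let-7f-5p between 38404 and 72453 in all 6 libraries. RPM and Kupffer cells were both rich in miR-146a-5p (88197 and 91333) and miR-21a-5p (70065 and 120402), which respond to inflammatory signalling. In the Kupffer cell library the most abundant miRNA was miR-122-5p, the dominant miRNA of hepatocytes, at 131501 (95% interval 131132 to 131871). The 5 most abundant miRNAs held 40.9% (RPM) to 51.6% (LSEC) of miRNA UMIs.

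miR-342-3p was highest in RPM, at 49297 CPM (interval 49114 to 49480). That was 2.90-fold (2.88 to 2.91) above cDC1, the next highest library at 17021, and 3.87-fold (3.83 to 3.91) above Kupffer cells at 12738. B cells at 13055 and cDC2 at 11248 lay near the Kupffer cell level. LSEC had 179, so that RPM exceeded LSEC 275-fold (267 to 283) and Kupffer cells exceeded LSEC 71.1-fold (68.9 to 73.3). The other arm, miR-342-5p, was scarce: 131 in Kupffer cells, 115 in RPM, 58.3 to 61.1 in B cells and dendritic cells, and 1.46 (36 UMIs) in LSEC. Its order between Kupffer cells and RPM, 1.14-fold (1.01 to 1.28), turned with DESeq2 factors (0.819), with all UMIs as the total (0.906) and after subtraction of the median row (0.919). As a list, the miR-342 locus was 2.14 log2 units above the other libraries in RPM, at percentile 99.725 of the matched random lists. The list holds only the 2 arms of the same hairpin, given above, so it adds no separate evidence. It left the highest 2.5% with TMM factors (97.015), DESeq2 factors (97.195), the median row subtracted (96.49) and a pseudocount of 1 (96.805). RPM stayed above cDC1 in miR-342-3p under every scaling, but only 1.45-fold with all UMIs of any RNA class as the total. Over Kupffer cells the fold passed 4 with TMM factors (4.29), DESeq2 factors (5.39) and all UMIs (4.87). Without the 3 most abundant miRNAs in the total it fell instead, as that total raised Kupffer cells against RPM by 0.326 log2 units. The Mir342 gene lies on chromosome 12, from 108658620 to 108658718 on the plus strand (GRCm38, GENCODE M21), in an intron of Evl, a regulator of actin filaments.

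**Figure D2:**
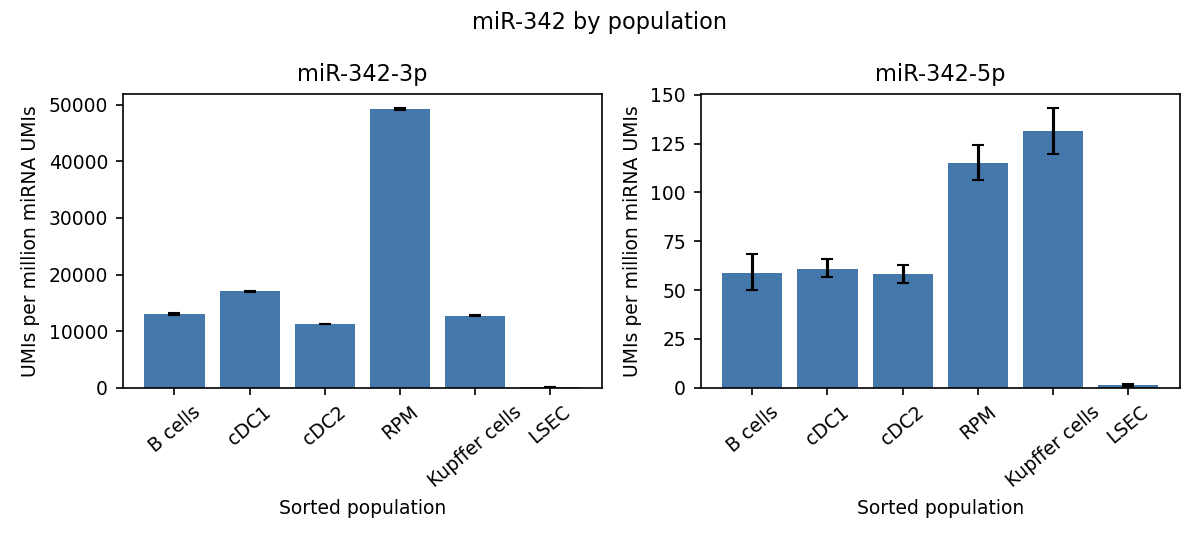
CPM of miR-342-3p and miR-342-5p in the 6 libraries; bars start at 0 and error bars are exact 95% Poisson intervals (counting error only). miR-342-3p is 49297 in RPM and 179 in LSEC, and miR-342-5p does not exceed 131 in any library.

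B cells were marked by 4 miRNAs. miR-150-5p, abundant in mature lymphocytes, stood at 38196 CPM, 4.10-fold (4.07 to 4.14) above cDC1. miR-155-5p, a miRNA of activated lymphocytes, reached 6858, 5.30-fold (5.19 to 5.42) above cDC1 and 68.0-fold above RPM. miR-296-3p (311) and miR-298-5p (254) were 5.32-fold and 4.43-fold above Kupffer cells, the next library. miR-20b-5p (1540) and miR-6974-5p (132) each stood 4.00-fold above the next library, just short of the rule. The B cell and lymphocyte list was 1.11 log2 units above the other libraries, at percentile 91.02, with 3 of 5 members up by 1 log2 unit or more. It was about as high in cDC2 (1.01, percentile 91.67, 3 of 5 up). In B cells, without its most abundant member, it stood at 1.85 and percentile 98.5. The miR-17-92 cluster, a proliferation-promoting cluster, was 1.72 log2 units higher (percentile 99.56), with 5 of 6 members up. It was also high in cDC1 (1.42, percentile 98.8, 6 of 6 up) and cDC2 (1.20, 97.71, 5 of 6 up), where it fell short with read counts (97.43) and without its most abundant member (95.71). miR-92a-3p stood at 39989 against 2236 in Kupffer cells. The pan-haematopoietic list was 3.34 log2 units higher (99.985), although miR-223-3p, a member made by myeloid cells, was only 2381 there against 27604 to 69463 in the myeloid libraries. Endothelial miR-126a-3p stood at 10683 in the B cell library, above the 873 to 2562 of the other splenic libraries. Hepatocyte miR-122-5p was likewise higher in B cells, at 666 against 39.1 (cDC2) to 95.9 (RPM) in the other splenic libraries. miR-150-5p lost its call with TMM factors (3.27-fold), with all UMIs as the total (3.64) and without the 3 most abundant miRNAs (3.73), and miR-298-5p lost it in the last of these (3.39). Without the Kupffer cell library, 8 miRNAs marked B cells.

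Dendritic cells shared 3 miRNAs. miR-138-5p was the clearest, at 5141 CPM in cDC1 and 2148 in cDC2, and the lower of these was 20-fold (17.8 to 22.5) above B cells at 107. GENCODE M21 places the Mir138-1 gene on chromosome 9 from 122682876 to 122682974 and Mir138-2 on chromosome 8 from 94324311 to 94324381 (GRCm38). miR-187-3p (1299 and 169) and miR-200a-3p (340 and 872) were 2.66-fold and 2.13-fold above the next library. miR-301a-3p, miR-222-3p and miR-33-5p came next with folds of 1.61, 1.55 and 1.43, which did not reach 2. With TMM and with DESeq2 factors miR-187-3p left the shared set and miR-222-3p entered it. The epithelial miR-200 list, named for tissue where these miRNAs keep the epithelial state, was 2.14 log2 units above the other libraries in cDC2, at percentile 99.73, with 5 of 5 members up. The pan-haematopoietic list was high in cDC1 (2.88, percentile 99.94) and cDC2 (1.98, 99.245). Without the Kupffer cell library 6 miRNAs were shared, and with all UMIs as the total 9 were.

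cDC1 and cDC2 had the highest Spearman correlation of the 15 pairs, 0.954, across miRNAs at 100 CPM or more in any library. Over all rows it was 0.819, below the 0.848 of B cells and cDC1. In cDC1, 3 miRNAs were at least 4-fold higher: miR-187-3p by 7.70-fold (7.33 to 8.09), miR-676-3p by 6.90-fold (6.42 to 7.41) and miR-365-3p by 5.58-fold (5.00 to 6.23). In cDC2, 4 were: miR-184-3p by 7.37-fold, miR-203-3p by 6.62-fold, miR-99a-5p by 6.20-fold and miR-181b-5p by 4.59-fold. miR-181a-5p, which tunes lymphocyte receptor signalling, was 3.91-fold higher in cDC2, at 17312 against 4426, and miR-34a-5p 3.03-fold. The B cell and lymphocyte list was 1.64 log2 units lower in cDC1, at percentile 0.005. That list without its most abundant member stood at -0.41 and percentile 10.01. Red cell miRNAs differed too: miR-451a was 3.37-fold and miR-486b-5p 3.17-fold higher in cDC1, and the erythroid list 1.04 log2 units (99.34, but 97.465 with a pseudocount of 50). Both miR-187-3p and miR-676-3p also marked cDC1 against all libraries: miR-187-3p was 7.70-fold above cDC2 and miR-676-3p 4.75-fold (4.31 to 5.24) above Kupffer cells, or 3.99-fold without the 3 most abundant miRNAs. miR-138-5p, miR-138-1-3p, miR-3968 and miR-148a-3p followed in cDC1 with folds of 1.70 to 2.39. No miRNA marked cDC2; the largest folds were 3.20 for miR-467e-5p, 3.11 for miR-200b-3p and 2.94 for miR-181c-5p. With TMM factors the split was 3 higher and 7 lower in cDC1, and with all UMIs 3 and 8. miR-184-3p lost its call with read counts, with DESeq2 factors and after subtraction of the median row. At 101 CPM in cDC2 it lay just above the minimum of 100. DESeq2 factors moved cDC1 against cDC2 by -0.0927 log2 units, so its fold rose there and the minimum took the call.

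Of the libraries, RPM was marked by 2 miRNAs, miR-708-5p at 439 CPM, 6.64-fold (5.72 to 7.76) above B cells, and miR-489-3p at 104, 4.99-fold (3.93 to 6.42) above Kupffer cells. miR-674-3p (3.77-fold), miR-143-3p (2.91-fold), miR-342-3p (2.90-fold) and miR-8114 (2.58-fold) followed without reaching 4. The macrophage and myeloid list was 2.18 log2 units above the other libraries (percentile 99.915), with 7 of 7 members up by 1 unit or more: miR-223-3p stood at 69463, miR-22-3p at 11669 and miR-511-3p, from an intron of the mannose receptor gene Mrc1, at 416. Maternally expressed miRNAs of the Dlk1-Dio3 imprinted cluster were 1.94 log2 units higher (99.455), with 7 of 8 up, among them miR-127-3p (220), miR-541-5p (127) and miR-379-5p (93.0). The erythroid list was 2.37 log2 units higher (99.42), led by miR-451a at 1158 and miR-486b-5p at 889; red pulp macrophages clear aged red cells. The miR-17-92 cluster was 1.18 log2 units below the other libraries, at percentile 0.715, or 3.52 without its most abundant member, and lower still in Kupffer cells (-1.75, percentile 0.14). Without the Kupffer cell library 13 miRNAs marked RPM, and with all UMIs of any class as the total 0 did. miR-489-3p lost its call with every other scaling, with read counts and after subtraction of the median row. At 104 CPM it lay just above the minimum of 100. TMM and DESeq2 factors moved Kupffer cells against RPM by -0.149 and -0.478 log2 units. Its fold over Kupffer cells thus rose with both, and the call was lost to the minimum.

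**Figure D3:**
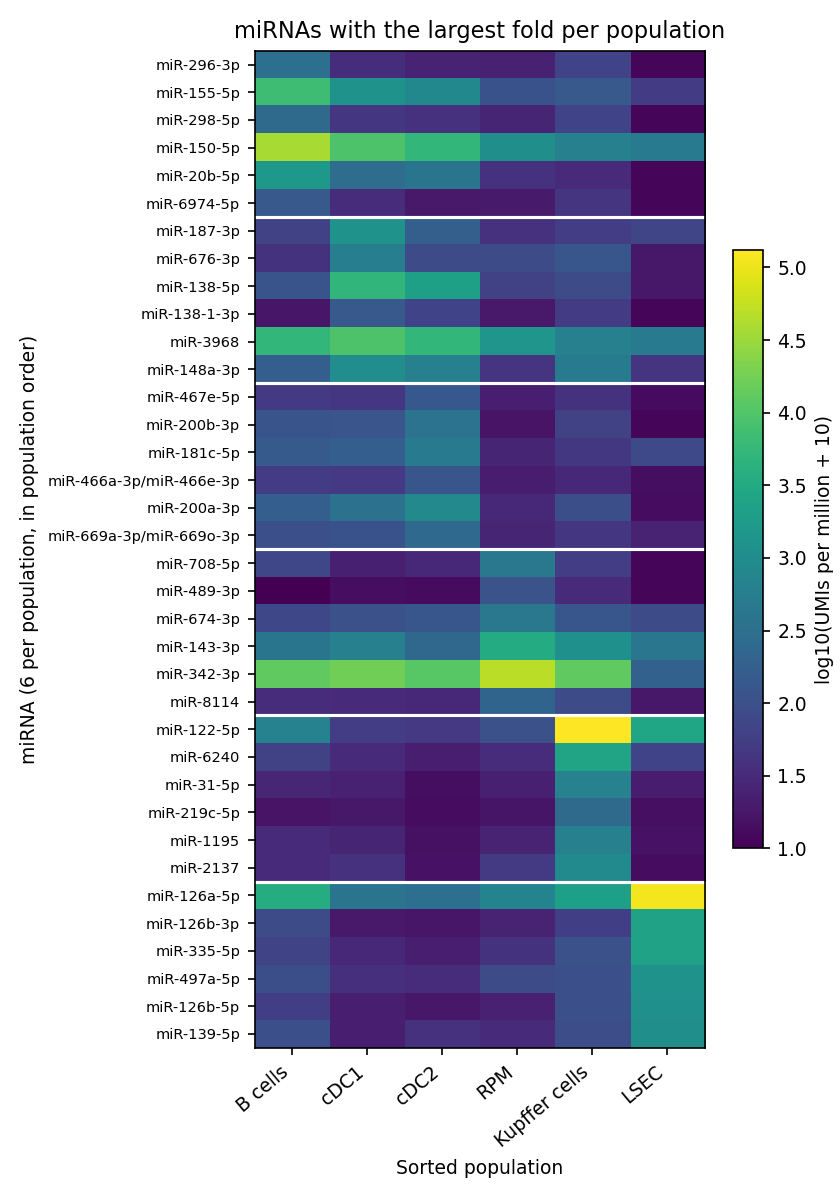
Level of the 6 miRNAs with the largest fold over the highest other library for each population (rows, white lines between populations) in the 6 libraries (columns), as log10(CPM + 10). The LSEC rows, such as miR-126a-5p at 109674, and the Kupffer cell rows, such as miR-122-5p at 131501, stand out more than those of cDC2, whose largest fold is 3.20.

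Kupffer cells and RPM, the macrophages of liver and spleen, shared 13 miRNAs that were at least 2-fold above all 4 other libraries. miR-3473e (10.8-fold over cDC1) and miR-127-3p (8.48-fold over B cells) led, followed by the red cell miRNAs miR-486b-5p (5.18-fold), miR-451a (4.91-fold) and miR-486a-5p (4.64-fold) and by miR-145a-5p (3.55-fold). miR-22-3p, at 7099 in the lower library, was 3.03-fold and miR-146a-5p, at 88197, 2.08-fold above the next. The macrophage and myeloid list was 1.51 log2 units high in Kupffer cells (percentile 98.645) and the inflammation-responsive list 1.83 (97.475, which entered the highest 2.5% with TMM factors at 98.615, DESeq2 factors at 99.58 and all UMIs at 99.21); the latter had 6 of 9 members up, among them miR-132-3p at 656, while miR-155-5p, at 130, was down. In RPM the inflammation-responsive list stood at -0.28 (percentile 13.22), with 3 members up and 4 down, and at -0.73 (2.3) without its most abundant member. With DESeq2 factors 5 miRNAs were shared, and with all UMIs 2, miR-3473e and miR-486b-5p.

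Between them, 48 miRNAs were at least 4-fold higher in Kupffer cells and 5 in RPM. miR-122-5p differed most, 1372-fold (1261 to 1495), and miR-122-3p was 63.1-fold higher. miR-6240 (109-fold), miR-31-5p (48.7-fold), miR-1195 (39.4-fold), miR-7015-5p (38.1-fold) and miR-219c-5p (37.6-fold) followed. miR-184-3p (22.8-fold), miR-2137 (22.1-fold) and miR-148a-3p (14.7-fold) completed the first 10. In RPM, miR-708-5p was 9.56-fold higher (8.18 to 11.2), miR-489-3p 4.99-fold, miR-93-5p 4.92-fold, miR-191-5p 4.43-fold and miR-3547-3p 4.20-fold. miR-322-5p, miR-142a-5p, miR-350-3p and miR-674-3p were 3.76-fold to 3.90-fold higher there, like miR-342-3p under the limit. Markers of other liver cells moved with the comparison: the hepatocyte list was 3.36 log2 units higher in Kupffer cells (percentile 99.81, 5 of 5 members up, but 96.115 without miR-122-5p) and the endothelial list 1.85 (99.935, 6 of 8 up). The median row of the Kupffer cell library was also higher, 37.0 against 7.59. The split of 48 and 5 became 35 and 10 with TMM factors, 22 and 16 with DESeq2 factors, 22 and 11 with all UMIs, 80 and 1 without the most abundant miRNAs, and 35 and 12 after subtraction of the median row.

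**Figure D4:**
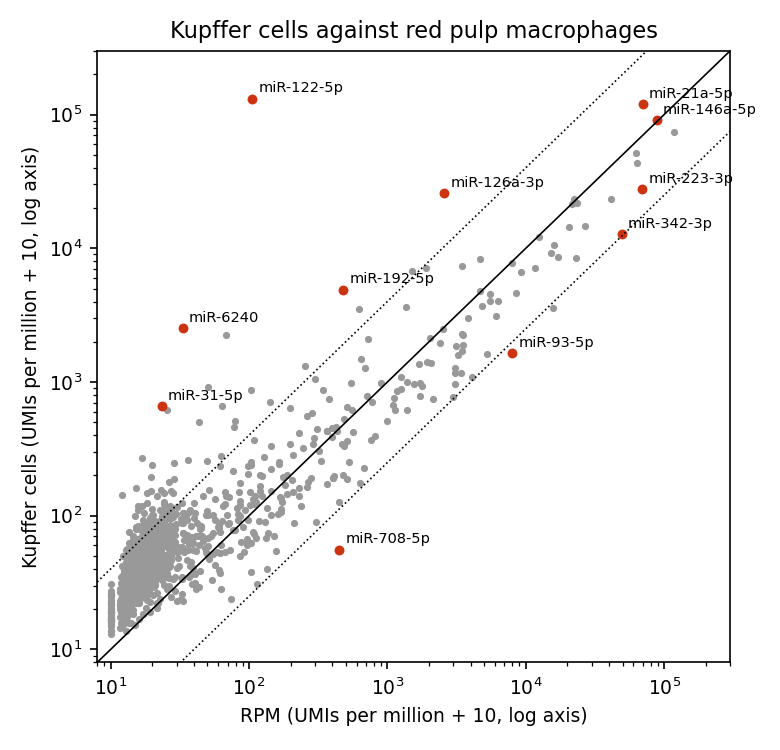
Each point is a miRNA, with its CPM plus 10 in RPM (x, log axis) and in Kupffer cells (y, log axis); the solid line marks equal levels and the dotted lines a 4-fold difference of the plotted values. By CPM without the added 10, 48 miRNAs at 100 CPM or more were at least 4-fold higher in Kupffer cells and 5 in RPM, some of which lie inside the lines, and miR-342-3p was 3.87-fold higher in RPM.

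Against all 5 other libraries, 24 miRNAs marked Kupffer cells. miR-122-5p was 49.6-fold above LSEC, the next library at 2649. miR-6240 (2528, 43.2-fold), miR-31-5p (654, 36.6-fold), miR-219c-5p (259, 29.7-fold), miR-1195 (606, 28.3-fold) and miR-2137 (906, 22.1-fold) followed. Within the hepatocyte list, which was 3.50 log2 units high (percentile 99.55, but 97.11 without miR-122-5p), miR-192-5p stood at 4898 and 10.5-fold above RPM, miR-194-5p at 1051 and 3.32-fold above LSEC, and miR-802-5p at 32.7, below the library's median row. The erythroid list was 3.11 log2 units high (98.94), with miR-144-3p at 245, but left the highest 2.5% with a pseudocount of 1 (96.47) and without its most abundant member (97.055). miR-10b-5p, on the endothelial list, was 139 in Kupffer cells and 19.9 in LSEC. At least 1000 CPM left 3 marking miRNAs, miR-122-5p, miR-192-5p and miR-6240, and a minimum of 10 gave 785. All UMIs as the total gave 10, and the total without the most abundant miRNAs 46.

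LSEC and Kupffer cells, both sorted from liver, differed in endothelial and haematopoietic miRNAs. In LSEC 26 miRNAs were at least 4-fold higher: miR-126a-5p 52.7-fold (51.5 to 53.8), miR-126b-3p 47.5-fold, miR-335-5p 25.3-fold, miR-195a-5p 20.7-fold and miR-497a-5p 14.5-fold. miR-139-5p, miR-126b-5p, miR-126a-3p, the joint row of miR-199a-3p and miR-199b-3p, and miR-100-5p were 9.64-fold to 13.1-fold higher. Kupffer cells had 92: miR-2137 by 238-fold, miR-223-3p by 229-fold (221 to 238), miR-486b-5p by 210-fold, miR-451a by 202-fold, miR-142a-3p by 114-fold, miR-1195 by 104-fold, miR-7015-5p by 85.2-fold, miR-342-3p by 71.1-fold, miR-122-5p by 49.6-fold and miR-21a-5p by 37.7-fold. The endothelial list was 2.39 log2 units lower in Kupffer cells (percentile 0.03) and the pan-haematopoietic list 4.61 higher (99.225, but 95.54 without its most abundant member). Against all other libraries the pan-haematopoietic list was low in Kupffer cells too (-1.94, percentile 0.875, 3 of 5 members down). The median miRNA was itself 1.34 log2 units higher in Kupffer cells, and other scalings moved this comparison by -1.26 (TMM), -1.91 (DESeq2) and -1.62 (all UMIs). The split of 92 and 26 then became 55 and 58, 33 and 77, and 31 and 65.

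Across all libraries 22 miRNAs marked LSEC. miR-126a-5p was 31.4-fold (30.7 to 32.0) above B cells and miR-126b-3p 29.4-fold; miR-335-5p, miR-497a-5p and miR-126b-5p were 25.3-fold, 14.5-fold and 12.7-fold above Kupffer cells, and miR-139-5p 12.3-fold above B cells. The endothelial list was 3.98 log2 units high (percentile 99.995), with 7 of 8 members up: miR-10a-5p stood at 23942, miR-125b-5p at 19281, let-7c-5p at 39830 and miR-100-5p at 2616. The stellate and mesenchymal list was 2.72 log2 units high (99.325, but 96.83 with a pseudocount of 50), with 3 of 5 up, led by the joint row of miR-199a-3p and miR-199b-3p at 8372; miR-143-3p (403) and miR-145a-5p (40.3) of smooth muscle were not up. The miR-23-27-24 clusters were 2.20 log2 units high (97.63), with 5 of 5 up, but left the highest 2.5% without the 3 most abundant miRNAs in the total (97.23) and without their most abundant member (96.14). Low lists were the pan-haematopoietic (-7.60, percentile 0.065), the epithelial miR-200 (-3.64, 0.125) and the erythroid (-2.44, 0.485), with 5 of 5 members down in each. Mir126a lies on chromosome 2 from 26591357 to 26591429 (GRCm38), within the endothelial gene Egfl7. The number marking LSEC was 43 with TMM, 52 with DESeq2 factors and 41 with all UMIs as the total.

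Both liver populations shared 12 miRNAs above all splenic libraries. miR-99b-5p (6.03-fold above B cells), miR-125a-5p (4.42-fold) and let-7e-5p (4.35-fold above cDC2), which come from 1 cluster, led the set, with LSEC the higher member. miR-199a-5p was 4.33-fold, miR-122-5p 3.98-fold (3.80 to 4.17) and miR-100-5p 2.94-fold above the next library. In each of these but miR-122-5p, Kupffer cells were the lower member. With all UMIs as the total 5 miRNAs were shared, 4 of them from the 12. miR-125a-5p, let-7e-5p and miR-100-5p were then not among them. With DESeq2 factors 10 were shared, 6 of them from the 12.

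Further list values lay at the edges. The endothelial list was low in cDC1 (-2.10, percentile 0.015), cDC2 (-1.57, 0.07) and RPM (-0.92, 0.59), and the stellate and mesenchymal list in cDC2 (-1.84, 0.64). The macrophage and myeloid list was low in B cells (-1.25, 0.745, but 9.55 with a pseudocount of 50) and cDC1 (-1.01, 2.42, but 2.94 with TMM factors and 11.18 without its most abundant member). The erythroid list was low in B cells (-1.22, 1.86, but 3.475 with DESeq2 factors) and cDC2 (-1.38, 1.04, but 8.195 with all UMIs and 33.585 with a pseudocount of 1), and the miR-23-27-24 clusters in B cells (-1.27, 1.71, but 7.76 without their most abundant member). In cDC1 against cDC2 the epithelial miR-200 list was lower (-1.23, 0.685), the pan-haematopoietic list higher (0.64, 99.74) and the stellate list higher (0.86, 98.24, but 92.995 without its most abundant member). Kupffer cells had the Dlk1-Dio3 cluster lower than RPM (-0.70, 0.395), and the erythroid list (4.59, 99.875) and the miR-342 locus (4.85, 99.04, but 95.75 with a pseudocount of 50) higher than LSEC.

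The remaining lists did not reach the highest or lowest 2.5% in any population. The let-7 family was between -0.48 (LSEC, percentile 86.965) and 0.27 (B cells, 55.165) and had its lowest percentile, 4.68, in cDC2; let-7e-5p ranged from 98.9 in cDC1 to 5721 in LSEC. The miR-29 family lay between -0.65 (LSEC) and 0.76 (RPM, percentile 80.02). The miR-30 family lay between -0.61 (B cells) and 0.62 (RPM, 74.085), with miR-30a-5p at 14856 in LSEC and 604 in cDC2. The proliferation-linked miR-15/16 list lay between -0.90 (LSEC) and 0.64 (cDC2, 78.065). Of 153 list comparisons, 44 lay among the highest or lowest 2.5% of the random lists.

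By Spearman correlation across 295 miRNAs, B cells were closest to cDC2 (0.900) and cDC1 (0.882). RPM had 0.786 with both cDC1 and Kupffer cells and 0.770 with cDC2. LSEC had 0.705 with RPM, 0.652 with Kupffer cells and 0.564 to 0.592 with the other libraries. Over all rows these orders changed. B cells were then closest to cDC1 (0.848), and RPM had its lowest value with Kupffer cells (0.761). LSEC had 0.777 with Kupffer cells and 0.776 with RPM.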

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

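All tests in this part were chosen after the results had been seen, apart from the search for repeats among the Kupffer cell miRNAs. The tables outside miRNA held high values that none of the comparisons used, and the highest of each table stood out as left unexamined. A row of transfer RNA for lysine (anticodon TTT) had 764671 UMIs in RPM, 4.89% of all UMIs there, against 0.0948% to 0.198% elsewhere. The row of the ribosomal 45S sequence had 6036565 UMIs in Kupffer cells, 46.9% of all UMIs there, against 4.10% (LSEC) to 15.0% (B cells). Whether its counts came from the precursor or from mature ribosomal RNA was not tested. The highest piRNA row had 29466 UMIs in cDC1 and 13786 in cDC2, and 81 to 170 in the other libraries.

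Hepatocyte miRNAs were abundant in the Kupffer cell library, although the gate for CD45 and F4/80 should remove hepatocytes. Scaling was tested first: over all scalings and the background subtraction the lowest fold of miR-122-5p above the next library was 13.3, which argues against the miRNA total as the cause. Hepatocyte RNA carried into the sort may account for it. Of the 4 other list members, 3 stayed above every other library after subtraction of the median rows. miR-802-5p did not, but at 32.7 CPM it lay below the median row of 37.0, so the subtraction fixed this outcome. The test therefore left the explanation open. Uptake or expression of miR-122, 13.2% of miRNA UMIs, by Kupffer cells themselves would look the same and cannot be told apart from 1 library. The comparisons of Kupffer cells that contain miR-122-5p, miR-192-5p and miR-194-5p rest on this point.

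Many low-abundance miRNAs marked Kupffer cells, 20 of them outside the hepatocyte and erythroid lists. A uniform background over all rows stays open: 20 of 20 were still past 4-fold after subtraction of the median row, but the minimum of 100 CPM by which they were chosen fixed this outcome for 18 of them. Only 13 still reached 100 CPM, and the number marking Kupffer cells went from 24 to 17. Fragments of repeats in longer transcripts could be read as these miRNAs: 30.0% of their hairpins (6 of 20, exact interval 11.9% to 54.3%) shared 20 bases with at least 5 other genes. Of the 22 miRNAs marking LSEC, 0 had such a hairpin (up to 15.4%). Some LSEC hairpins, such as that of miR-126a, were counted once per arm, so this upper end is too low. The 6 were miR-1195, miR-3470a, miR-3470b, miR-466i-5p, miR-706 and miR-709; the share neither reached nor excluded the predicted 50%, the 45S sequence was not searched, and expression by Kupffer cells was not tested.

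The arms of miR-126a and miR-142a had another balance in the Kupffer cell library. The log2 ratio of 5p to 3p was -3.63 for miR-126a, against -1.84 to -1.21 in the 5 other libraries, and -4.43 for miR-142a, against -2.55 to -2.17. A uniform background would move both ratios toward 0, while both lay further below 0 than in every other library. The smaller departure from the median of the others was -1.98. As the pattern had been picked for this direction, that was no test of a background. Subtraction of the median row left the ratios at -3.66 and -4.48. A general loss of 5p arms was argued against by the median difference from RPM over 21 other hairpins, -0.24 (SD 1.07). That difference was -1.80 for miR-126a and -1.98 for miR-142a, although single hairpins reached -2.45. A similar SD across hairpins was seen without Kupffer cells: 1.15 for B cells against RPM and 1.1 for LSEC against RPM. It was 0.84 for cDC1 against RPM and 0.41 for cDC1 against cDC2. As miR-126a and miR-142a were picked after the values had been seen, a common spread between hairpins stays open for their shifts from RPM. A candidate source of miR-126a in Kupffer cells is carried-over endothelial RNA, which the gate for CD45 should remove; its ratio differed from that of LSEC by -2.42, but miR-142a, nearly absent from LSEC, shifted as well, so the ratio cannot settle it. A difference in arm use between cell types remains open and untested.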

How the results depend on the processing

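Subtraction of the median row and omission of the Kupffer cell library were chosen after the data had been seen. No paired analysis was possible because each population has 1 library, and for the same reason no replicate could be left out. The 87 folds of miRNAs ranked for a population or pair had been picked for their size. That choice largely fixed whether they could turn, so their direction is no test of the scaling. A fold that was not picked by size did turn, as given in the next paragraph. Among the 87, no fold turned under any scaling. They were multiplied by 0.267 to 3.75 with DESeq2 factors, 0.418 to 2.54 with TMM factors, 0.326 to 3.06 with all UMIs, 0.847 to 1.38 with reads, and 0.910 to 11 after background subtraction, and 76 (TMM) to 85 (reads) kept their side of 4. Of the 44 list comparisons among the highest or lowest 2.5% of random lists, 33 stayed there without the most abundant member, 38 with a pseudocount of 50, 39 with 1, and 41 to 43 under the scalings, reads included. Depth limits mostly B cells, where 10 UMIs are 3.57 CPM.

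The values that moved follow. A change of the total multiplies every fold between a pair of libraries by the same factor. With all UMIs as the total, that factor follows the miRNA share of all UMIs. The share was 64.3% in B cells, 72.6% in cDC1, 79.1% in cDC2, 36.2% in RPM, 28.8% in Kupffer cells and 88.2% in LSEC. For the other settings the cause was not tested. With read counts, RPM had 1 marking miRNA, miR-342-3p was 3.01-fold above cDC1, and the lowest miRNA share of all UMIs, 28.8% in Kupffer cells, was 23.6%. With TMM factors, 1 miRNA marked cDC2, 1 RPM and 43 LSEC. Kupffer cells had 10 lower than RPM, and 55 higher and 58 lower than LSEC; cDC1 had 7 lower than cDC2, macrophages shared 6, and miR-342-3p was 2.72-fold. With DESeq2 factors, 7 marked B cells, 1 RPM, 11 Kupffer cells and 52 LSEC. Kupffer cells had 22 higher and 16 lower than RPM and 33 higher and 77 lower than LSEC, macrophages shared 5, miR-342-3p was 2.72-fold, and miR-342-5p turned toward RPM (0.819). With all UMIs as the total, 0 marked RPM, 10 Kupffer cells and 41 LSEC. Kupffer cells had 22 higher and 11 lower than RPM and 31 higher and 65 lower than LSEC; cDC1 had 8 lower than cDC2. Macrophages shared 2, dendritic cells 9 and liver cells 5, miR-342-3p was 1.45-fold and miR-342-5p turned (0.906). Without the 3 most abundant miRNAs in the total, 2 marked B cells, 1 cDC1, 1 RPM and 46 Kupffer cells, which had 80 higher and 1 lower than RPM; miR-342-3p was 2.75-fold and miR-342-5p 1.43-fold. After background subtraction 8 marked B cells, Kupffer cells had 12 lower than RPM, and miR-342-5p turned (0.919). Without the Kupffer cell library, 8 marked B cells, 1 cDC2 and 13 RPM, and dendritic cells shared 6.

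The rules themselves set other counts. At 10 CPM, 785 marked Kupffer cells, which had 1155 higher than RPM and 1596 higher than LSEC; cDC1 had 69 higher and 8 lower than cDC2, and macrophages shared 72, dendritic cells 5 and liver cells 37. The correlation of cDC1 and cDC2 was then 0.815, and over all rows B cells and cDC1 were the closest pair. At 1000 CPM, 2 marked B cells, 1 cDC1, 0 RPM and 3 Kupffer cells. Kupffer cells had 8 higher and 2 lower than RPM and 21 higher than LSEC, cDC1 had 1 higher and 1 lower than cDC2, and 3, 1 and 5 were shared by macrophages, dendritic cells and liver cells. By the lower interval end, 1 marked RPM and Kupffer cells had 3 lower than RPM. At 2-fold, 13 marked B cells, 4 cDC1, 12 cDC2, 11 RPM and 44 Kupffer cells. Kupffer cells had 75 higher and 38 lower than RPM and 44 lower than LSEC, and cDC1 had 20 higher and 30 lower than cDC2. At 4-fold, 5, 1 and 4 were shared by macrophages, dendritic cells and liver cells. Against the median of the other libraries, 31 marked B cells, 23 cDC1, 29 cDC2, 27 RPM, 69 Kupffer cells and 47 LSEC.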

Other observations

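Counts assigned to host transcripts of several miRNAs, which sat outside the comparisons, also differed between libraries. They come from small RNA libraries, so they do not measure the level of whole transcripts. GENCODE M21 places Mir155 within an exon of Mir155hg, so pieces of the miR-155 hairpin may be counted in it. This was not tested. Mir155hg, the precursor of miR-155, had 988 UMIs per 1000000 UMIs of any class in B cells, 108 in cDC1, 87.7 in cDC2 and 7.61 to 10.7 in RPM, Kupffer cells and LSEC. Dnm3os, the transcript that carries miR-199a and miR-214, had 3076 in LSEC and 23.6 to 112 elsewhere. A330023F24Rik, which carries miR-29 genes, was flatter, from 869 in Kupffer cells to 2476 in LSEC. Gas5, a host of small nucleolar RNAs, was highest in B cells (10018), followed by cDC1 (5514), cDC2 (3931), RPM (1945), Kupffer cells (1340) and LSEC (768). The nuclear RNAs Malat1 and Neat1 stood at 2990 and 2044 in Kupffer cells, against 75.9 to 193 and 41.0 to 96.6 in the other libraries.

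Transfer RNA in RPM was not 1 row alone. Valine isotypes held 31.7% of its transfer RNA UMIs and lysine 17.1%, and valine alone was 15.8% of all UMIs of that library. In Kupffer cells glutamate was the largest isotype with 25.5%, and in LSEC valine with 22.0%.

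The highest piRNA row followed the dendritic cells as miR-138-5p did: 1989 UMIs per 1000000 UMIs of any class in cDC1, 1029 in cDC2 and 3.03 to 39.0 in the others. The name of that row places it on chromosome 9, where Mir138-1 also lies. The build of this position is not given, so an overlap could not be tested.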
